A study of Gallus gallus with 6 samples.

How the data were processed

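RNA was measured in cultured chicken embryo dermal myofibroblasts with and without an inhibitor of the type I TGF-beta receptor kinase, 3 arrays per group. Per the labels' protocols, the medium held 4% serum from fetal calves and 2% serum from chickens, total RNA was extracted with Trizol, and biotinylated cRNA was made from 5 ug of it. The deposited values are log2 intensities, 1 per probe set and array, made by the submitters with GCRMA, a background correction, normalization and summary of Affymetrix probes, and Partek 6.4 is named beside it, per the submitters' processing notes. The GCRMA settings and version are not given in the sources used here. That the values are on a log2 scale was read from the values themselves, which ran from 1.12 to 16.0 with array medians of 2.98 to 3.03. GCRMA gathers dim probe sets near a floor of about 2 to 3, which hides differences there and makes a fold against such a group depend on the floor. At the other end, probe sets close to the highest values can respond less than in proportion. The number of arrays limits the precision. Scanner files were not used here.

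Groups and replicate numbers came from the sample titles. The labels call the samples biological replicates and do not say whether cultures came from separate embryos, so the p-values measure the spread between these samples. No pair of arrays held identical values. The numbers pair the samples: deviations from the group means correlated between same-numbered arrays at 0.63, 0.67 and 0.45 for replicates 1, 2 and 3, and between unlike numbers at -0.45 to -0.14. The pairing comes from this check, as the labels do not describe it. Deviations sum to 0 within each group, so the negative values of unlike numbers are tied to the positive ones and add no separate evidence.

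Of 38535 probe sets, 96 controls were left out, and 16567 (43.1%) passed a filter of a log2 value of at least 4 in at least 3 of the 6 arrays, blind to the group. Gene names came from the platform annotation supplied with the data, which can be old: 27178 probe sets carry 1 symbol, 177 several and 11180 none. Gene identifiers of 26863 of the 27178 were found in a gene table of assembly GRCg7b, which changed 0 symbols and was used only for names, synonyms and chromosome assignment. List members matched only through a synonym, such as ATVR1 for ACVR1, CTSV for CTSL and ALAS1 for ALAS2, can be related genes rather than the same gene. Among tested probe sets 13710 had 1 symbol, 68 several and 2789 none; those with several or none stayed in the tests and were not named. A gene was represented by its tested single-symbol probe set with the highest mean over all 6 arrays, which gave 8124 genes. Other probe sets disagreed in call with the representative for LOXL3, EGR1, WNT2B, PECAM1, MITF, CXCL12, FN1, CP, PDE4B, THBS1, CDKN1B, TES, GPC4 and LRRC32, and in sign for FN1, ACTB, COL3A1 and CLDN5, among the 194 genes followed across the alternatives.

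Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), as inhibitor minus DMSO, two-sided, with no replicate block and with Benjamini-Hochberg adjustment over all tested probe sets; a call is an adjusted p under 0.05. Errors of log2 differences are standard errors of that fit. The 27 gene lists were drawn from textbook knowledge, and the 23 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists. Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation rests on the few residual degrees of freedom of 6 arrays, and its lowest adjusted p over the 23 lists was 0.221.

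The groups, tests, gene lists and alternatives were chosen before the data were examined. So was the rule for named genes: the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, skipping placeholder symbols; in each list, the up to 4 tested members with the largest log2 difference; and ACTA2, TAGLN, CNN1, SMAD7, CCN2, TGFBI, COL1A1, COL1A2, FN1, TGFBR1, TGFBR2, GAPDH and ACTB. This rule named 130 genes. Of these SMAD2, MYLK, COL11A1, LUM, ITGA3, CCNE2, CDC45, GADD45G, EGR1, SOX5, DLX6, RUNX2, TNNT3, CDH3, FABP7, NEFL, CD74, CTSS, PMVK, INSIG1, STARD4, GUSB, HPRT1 and TBP did not pass in limma without the replicate block. With it, SMAD2 (1.14 ± 0.46, limma adjusted p 0.0022), MYLK (1.51 ± 0.70, 0.0061), COL11A1 (-1.95 ± 0.69, 0.0041), LUM (-1.95 ± 0.55, 0.0042) and ITGA3 (1.34 ± 0.36, 0.0035) passed. So did CDC45 (-0.51 ± 0.13, 0.0246), GADD45G (-0.97 ± 0.52, 0.0048) and EGR1 (-0.84 ± 0.26, 0.0087). The errors given for these genes are those of the fit without the block, whereas the adjusted p-values come from the fit with it. A dimmer EGR1 probe set passed without the block (-1.04 ± 0.24, 0.0352). CCNE2, SOX5, DLX6 and RUNX2 did not pass with the block. The remaining genes of this list have no value in the report. Other genes of the rule that did not pass without the block, ACTA2, TAGLN, SMAD7 and COL1A1 among them, appear with values in the results. A fixed gene of the rule and a gene list written after the data were seen are not reported here. Further genes chosen after their values were seen bring the number followed across the alternatives to 194, and not all of them are named in the report. Genes named outside the 194, such as SLC25A6 and HINTW, were chosen after their values were seen too.

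The alternatives were no filter, a filter at a log2 value of 6, quantile normalization, median centring, eBayes without a trend, robust eBayes, a linear model without moderation, the replicate number as a block, leaving out each array in turn, the mean of a gene's probe sets, and both other list tests. Leaving out probe sets that can bind several transcripts was added after the data were seen. The procedure was tested on simulated data for the inhibitor and DMSO arrays with 16567 probe sets: it recovered 44% of 50 probe sets changed by a log2 difference of 1, and 90%, 92% and 98% of 50 each changed by 2, 3 and 4. Of its 173 calls 4 were among unchanged probe sets, and a list of 43 genes shifted by 0.5 was found at a camera adjusted p of 2.86e-29, with 0 other lists called. The simulated noise was independent between probe sets and arrays, with no correlation between genes and no replicate pairs. The real cell cycle list has an estimated correlation of 0.42, so the simulated list result says little about list calls on the real arrays.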

Results

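Dermal myofibroblasts, fibroblasts that make matrix and contractile proteins, were grown from skin explants of brown Leghorn chicken embryos at day 10 of incubation. The cultures received TGFBR1 Kinase Inhibitor II at 500 nM for 48 h, a small molecule that blocks the kinase of the type I TGF-beta receptor, or only its solvent, DMSO, at 0.1%. Each condition had 3 biological replicates, and each replicate was hybridised to an Affymetrix chicken array, giving 6 arrays. Per the series title, the comparison addresses which genes TGF-beta controls in these cells. A log2 value of at least 4 was reached by 16356 to 16594 probe sets per array. The mean correlation of an array with the others of its group was 0.978 to 0.984, and with the arrays of the other group 0.947 to 0.952. The first principal component held 59.1% of the variance and separated inhibitor from DMSO arrays, and the next held 18.4% and set replicate 2 of both groups apart from the rest. The 3′ minus 5′ difference of the ACTB control probe sets, a sign of RNA integrity and labelling, was 1.43 ± 0.05 in DMSO and 1.57 ± 0.08 in inhibitor arrays (log2, SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). The same measure gave p = 0.5 for GAPDH and p = 1 for EEF1A1 in the exact test.

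Inhibition of the receptor kinase moved many genes in both directions, several of them by more than 40-fold. ARHGAP15, a GTPase-activating protein, rose 99.1-fold (log2 difference 6.63 ± 0.30, SE, 3 arrays per group), and RASL11A, a Ras-like protein, rose 56.9-fold (5.83 ± 0.24). EXFABP, a secreted lipid-binding lipocalin of chicken cells, rose 54.9-fold (5.78 ± 0.58), VTN, the adhesion protein vitronectin, 48.6-fold (5.60 ± 0.22) and SOD3, the extracellular superoxide dismutase, 48.0-fold (5.58 ± 0.55, and 6.22 without DMSO 2). The matrix protein gene SPON2 fell to levels 46.5-fold lower (-5.54 ± 0.28), the transmembrane collagen COL23A1 41.3-fold lower (-5.37 ± 0.35) and TGFBI, a secreted matrix protein named for its induction by TGF-beta, 19.1-fold lower (-4.25 ± 0.49). In all, 664 of 8124 tested genes rose and 609 fell at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 16567 probe sets).

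Among the other large rises were CCDC3 (5.60 ± 0.28), KRT7, a keratin of simple epithelia (5.37 ± 1.01), ADAMTSL1 (5.01 ± 0.24), TNFSF4, the ligand OX40L (4.96 ± 0.44), the angiotensin receptor AGTR2 (4.88 ± 0.49), the complement regulator CFI (4.86 ± 0.90) and NPR3, the clearance receptor for natriuretic peptides (4.56 ± 0.34). The other large falls were GAS2 (-5.07 ± 0.52), the growth factor pleiotrophin, PTN (-4.83 ± 0.42), WNT5B (-4.59 ± 0.36), the cyclic AMP phosphodiesterase PDE4D (-4.01 ± 0.18), CACFD1 (-3.99 ± 0.28), MAP1LC3C (-3.98 ± 0.18), the receptor tyrosine kinase RET (-3.93 ± 0.38), ANKRD1 (-3.90 ± 0.70) and DNAH10 (-3.87 ± 0.40). ARHGAP15, RASL11A, CCDC3, VTN and AGTR2 had DMSO means under 4, and GAS2, PTN, PDE4D and DNAH10 had inhibitor means under 4, where GCRMA values crowd at a floor, so the sizes of these folds depend on that floor. The same holds, among genes named later, for the rises of MYH11, NID1, PLAT, NRG1, EDN1 and LPIN1 and the falls of INHBB, COL15A1, HAS2, PLAU and DUSP4. ARHGAP15, KRT7 and CACFD1 are each represented by a probe set that can also bind other transcripts. Dimmer probe sets passed with sizes over 2-fold apart from those printed for SPON2 (-3.37), COL23A1 (-1.91), ADAMTSL1 (1.78), PTN (-3.57) and PDE4D (-2.62) and, among genes named later, BHLHE40 (-1.76), MYOCD (-0.68), COL12A1 (-2.20), SDC1 (-1.54), FZD4 (3.47) and PECAM1 (-1.90). The limma adjusted p of the largest rises and falls lay between 0.000267 for VTN and 0.0189 for KRT7. The call of KRT7 was lost without any single inhibitor array (limma adjusted p 0.0557 to 0.0607), that of CFI likewise (0.0526 to 0.0591) and that of ANKRD1 without inhibitor 3 (0.0504). With all 6 arrays and the replicate number as a block, KRT7, CFI and ANKRD1 passed at limma adjusted p 0.00526, 0.00507 and 0.000784. The size of the KRT7 rise was 4.11 without DMSO 1 and 6.17 without DMSO 2, that of CFI 3.73 and 5.45 without the same arrays, and the falls of GAS2 and ANKRD1 were -5.67 without DMSO 2 and -3.20 without DMSO 1.

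**Figure D1:**
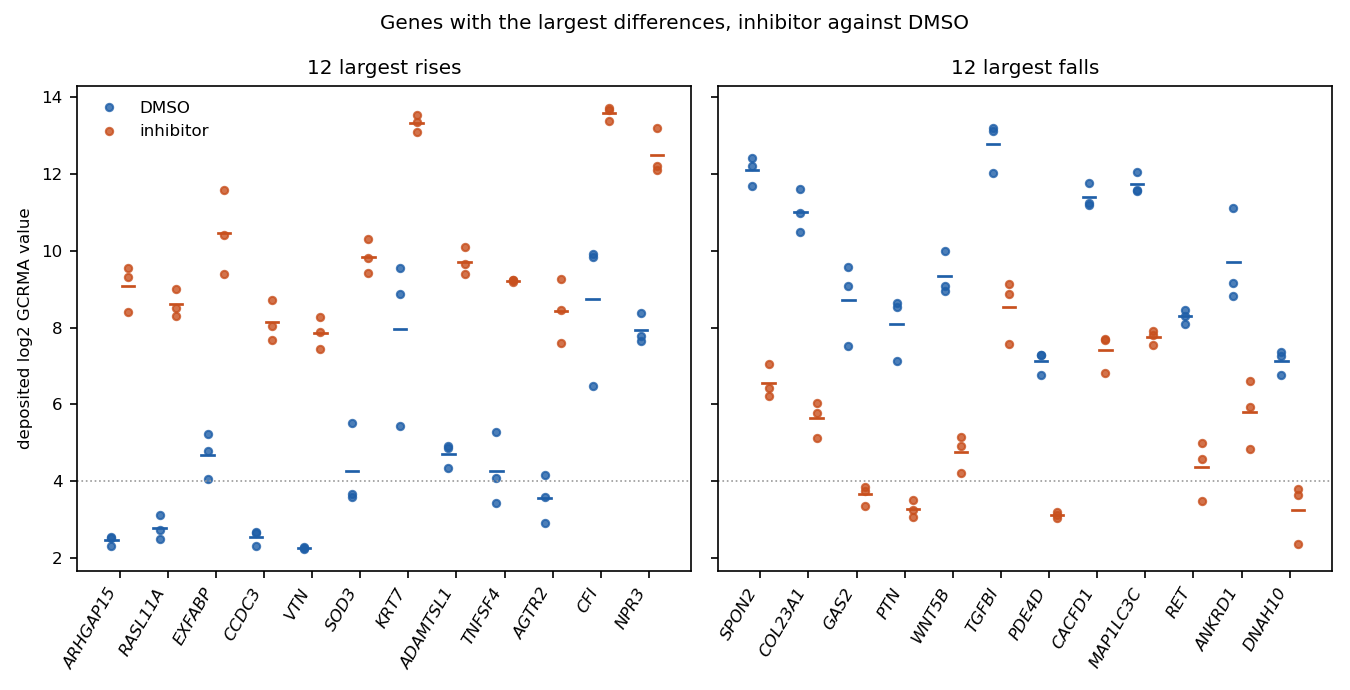
Deposited log2 GCRMA values of the 12 genes with the largest rise (left) and the 12 with the largest fall (right), 1 point per array and a bar at each group mean. The dotted line marks the filter level of 4; ARHGAP15 has a mean of 2.46 in DMSO and 9.09 in inhibitor arrays, and SPON2 a mean of 12.1 in DMSO and 6.56 in inhibitor arrays.

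By probe set, 1205 rose and 1078 fell, 13.8% of those tested, and 1105 of the 2283 differed at least 2-fold (595 up, 510 down). At the gene level 308 rose and 259 fell at least 2-fold. With median centring falls outnumbered rises, with 1124 probe sets up and 1229 down and 621 genes up and 701 down. The median log2 difference over the tested probe sets was 0.01. With the replicate number as a block, limma called 4661 probe sets (2470 up, 2191 down), among them all 2283, and 2570 genes (1339 up, 1231 down). The count was 1107 probe sets and 624 genes without DMSO 1, 1495 and 840 without DMSO 2, 1267 and 701 without DMSO 3, 1206 and 671 without inhibitor 1, 1285 and 706 with no filter, and 996 and 567 without moderation. Of 147 called genes followed across the settings, 94 kept the call without each single array and 53 lost it without at least 1. All 147 were also called with the replicate block. The fits without 1 array have no block, so spread between the replicate numbers counts against a call there. A call lost in such a fit does not by itself show that the change differed between the replicate numbers.

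Some known targets and feedback genes of SMAD signalling fell. Besides TGFBI they were BHLHE40, a transcriptional repressor (-3.16 ± 0.18, 8.91-fold lower), SMURF2, a ubiquitin ligase for TGF-beta receptors and SMADs (-2.86 ± 0.09), LDLRAD4 (-2.16 ± 0.22) and PMEPA1 (-1.93 ± 0.12), membrane proteins that limit SMAD activation, and the transcription factor SNAI2 (-1.24 ± 0.29). Of the 20 list members tested, 6 fell, 7 adjusted over the list alone and 9 with the replicate block, and the other 14 did not pass the test. The list lay lower than the other genes (camera adjusted p = 0.000225 over 23 lists), a call that was lost with camera's adjusted p = 0.221 with an estimated correlation. Members that did not pass included SKIL (-1.98 ± 0.67, and -1.34 without inhibitor 2; limma adjusted p 0.106, and 0.00123 with the replicate block), the inhibitory SMAD7 (-0.33 ± 0.21; 0.369) and CCN2, connective tissue growth factor (-0.14 ± 0.05; 0.119), whose mean level of 15.2 in DMSO arrays lay close to the top of the scale. The SNAI2 call was lost without any array other than inhibitor 1 (limma adjusted p 0.0614 to 0.117).

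Among ligands, receptors and SMADs of the TGF-beta and activin branch, 2 of 18 tested genes rose and 5 fell, against 3 and 6 adjusted over the list alone and 4 and 8 with the replicate block. The activin subunits INHBB (-2.37 ± 0.17) and INHBA (-1.84 ± 0.10) and the latent TGF-beta binding protein LTBP1 (-1.72 ± 0.15) fell, as did the inhibited receptor's own transcript, TGFBR1 (-0.64 ± 0.11), and ATVR1 (-0.56 ± 0.06), matched to the activin type I receptor ACVR1 only through a synonym. LRRC32, which holds latent TGF-beta at the cell surface (1.03 ± 0.13), and the activin receptor ACVR2A (0.73 ± 0.13) rose. The list as a whole did not pass (camera adjusted p = 0.162). The TGFBR1 call was lost without inhibitor 1 (limma adjusted p 0.0585), and that of ACVR2A without DMSO 1 (0.0606) or DMSO 2 (0.0540). Of 2 other LRRC32 probe sets 1 did not pass (0.91 ± 0.32). TGFBR2 did not pass the filter.

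Genes of the BMP branch that passed the test mostly rose. The inhibitors of differentiation ID2 (2.74 ± 0.19, 6.69-fold), ID1 (1.94 ± 0.36), ID4 (0.90 ± 0.14) and ID3 (0.80 ± 0.20), which BMP signalling is known to induce, rose, and so did SMAD9, a BMP-branch SMAD (1.83 ± 0.29), whereas the homeobox gene MSX1 fell (-1.43 ± 0.24). Of 15 tested members 5 rose and 1 fell, 7 and 1 adjusted over the list alone, and 8 and 2 with the replicate block; the list's camera adjusted p was 0.110, upward. Leaving out 1 array ended the call of ID1 without DMSO 1 (limma adjusted p 0.0689), of MSX1 without DMSO 1 or inhibitor 1 (0.0580 and 0.0527) and of ID3 without any array other than inhibitor 2 (0.0659 to 0.131).

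The contractile genes of smooth muscle did not move together. MYOCD, the coactivator that drives smooth muscle gene expression, fell 7.46-fold (-2.90 ± 0.35), enteric smooth muscle actin ACTG2 fell (-2.24 ± 0.53) and so did tropomyosin TPM1 (-0.36 ± 0.06), whereas the smooth muscle myosin heavy chain MYH11 rose 5.64-fold (2.50 ± 0.36). ACTA2, the smooth muscle actin used as the myofibroblast marker, stood at 0.46 ± 0.26 (limma adjusted p 0.301) and transgelin, TAGLN, at -0.18 ± 0.09 (0.253). ACTA2 rests on 1 tested probe set with a DMSO mean of 7.43, against 13.6 for TAGLN. How well that probe set measures ACTA2 was not tested. Of 18 tested members 1 rose and 3 fell, 1 and 5 adjusted over the list alone and 2 and 4 with the replicate block; camera gave an adjusted p of 0.780, with a median of 0.14, a mean of -0.03 and a downward test direction. The probe set that represents TPM1 has a DMSO mean of 15.4, and 3 dimmer TPM1 probe sets fell by 1.24, 2.29 and 1.86 on the log2 scale. The ACTG2 call was lost without any array other than DMSO 2 (limma adjusted p 0.0510 to 0.112). With all 6 arrays and the replicate block it passed at limma adjusted p 0.000666. CNN1 was not named on the array.

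**Figure D2:**
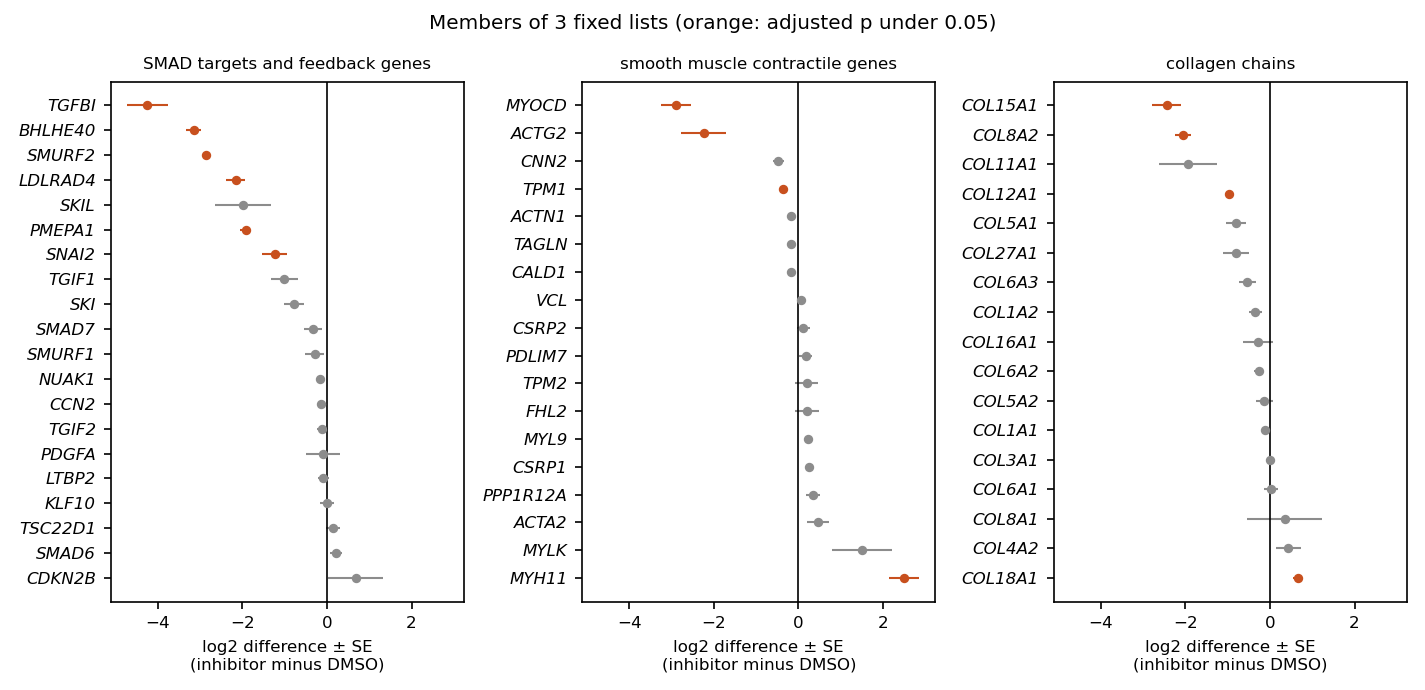
Log2 difference, inhibitor minus DMSO, with its SE, of each tested member of 3 gene lists (3 arrays per group); orange points passed an adjusted p of 0.05 in limma. TGFBI is lowest in the left panel at -4.25, MYOCD at -2.90 and MYH11 at 2.50 mark the ends of the middle panel, and COL15A1 at -2.44 is lowest in the right panel.

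Among genes that process and crosslink collagen, 8 of 18 tested fell and 1 rose, 9 and 1 adjusted over the list alone, and 13 and 1 with the replicate block. The list's camera adjusted p was 7.44e-05, downward, a call that was lost at adjusted p = 0.370 with an estimated correlation. The procollagen proteinase TLL1 (-2.26 ± 0.26), the proteinase enhancer PCOLCE2 (-1.61 ± 0.24), the prolyl hydroxylase P4HA2 (-1.28 ± 0.08) and the lysyl hydroxylase PLOD2 (-0.63 ± 0.09) fell. Of the lysyl oxidases LOXL2 (-1.01 ± 0.19) and LOXL3 (-1.09 ± 0.21) fell and LOXL1 rose (0.83 ± 0.19). A dimmer LOXL3 probe set did not pass (-0.21 ± 0.32). The LOXL1 call was lost without DMSO 1, DMSO 2, DMSO 3 or inhibitor 3 (limma adjusted p 0.0607 to 0.0992), that of LOXL2 without DMSO 1, DMSO 2 or inhibitor 1 (0.0523 to 0.0596) and that of LOXL3 without DMSO 1, DMSO 3, inhibitor 1 or inhibitor 2 (0.0529 to 0.0840).

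Collagen chains differed from one another. The basement membrane-associated COL15A1 (-2.44 ± 0.34, 5.42-fold lower), the short-chain COL8A2 (-2.05 ± 0.19) and COL12A1, which lies on the surface of collagen fibrils (-0.96 ± 0.09), fell, and COL18A1 rose (0.65 ± 0.11). The main fibrillar chains did not pass: COL1A1 stood at -0.11 ± 0.07 (limma adjusted p 0.345), COL3A1 at 0.00 ± 0.07 (0.980) and COL1A2 at -0.35 ± 0.15 (0.189, and 0.0220 with the replicate block). Of 17 tested chains 1 rose and 3 fell, 1 and 4 adjusted over the list alone, and 1 and 8 with the replicate block. The list's camera adjusted p was 0.0402, downward, and the call was lost at adjusted p = 0.534 with an estimated correlation, at 0.0654 without DMSO 1, 0.102 without DMSO 3 and 0.131 without inhibitor 2. The COL18A1 call was lost without DMSO 1 or inhibitor 1 (limma adjusted p 0.0517 and 0.0523).

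Matrix glycoproteins showed large changes of opposite sign. Periostin, POSTN (-2.81 ± 0.55), cartilage oligomeric matrix protein COMP (-2.71 ± 0.30, 6.53-fold lower), tenascin TNC (-2.65 ± 0.41), thrombospondin THBS2 (-2.48 ± 0.53), FBLN5, an elastic fibre protein (-1.03 ± 0.14), and SPARC (-0.57 ± 0.08) fell, while EFEMP1 (4.20 ± 0.35, 18.4-fold higher), CCN3 (2.86 ± 0.73) and the basement membrane nidogens NID1 (2.81 ± 0.36) and NID2 (2.27 ± 0.29) rose. Of 25 tested members 4 rose and 9 fell, 5 and 10 adjusted over the list alone and 6 and 12 with the replicate block (camera adjusted p = 0.131). Fibronectin, FN1, stood at -0.09 ± 0.07 (limma adjusted p 0.400) by a probe set at 15.9 in DMSO arrays; 5 of its 7 other probe sets had the opposite sign, and 2 of these passed at 0.53 and 0.49. The CCN3 call was lost without any array other than DMSO 2 (limma adjusted p 0.0637 to 0.131), that of POSTN without any other than inhibitor 3 (0.0556 to 0.0780) and that of THBS2 without DMSO 1, DMSO 3, inhibitor 2 or inhibitor 3 (0.0515 to 0.0962). With all 6 arrays and the replicate block, CCN3 and POSTN passed at limma adjusted p 0.00122 and 0.00368. The difference of CCN3 was 2.13 without DMSO 1 and 3.49 without DMSO 2, and that of POSTN -3.47 without inhibitor 3.

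Proteoglycan and hyaluronan genes included large falls. The hyaluronan synthase HAS2 (-3.77 ± 0.38, with an inhibitor mean under 4), biglycan, BGN (-3.65 ± 0.27), syndecan SDC1 (-3.64 ± 0.09, 12.5-fold lower, limma adjusted p 8.7e-05) and the hyaluronan receptor CD44 (-1.25 ± 0.23) fell, and glypican GPC4 (1.42 ± 0.24) and versican, VCAN (0.98 ± 0.15), rose. That is 2 up and 4 down of 12 tested, 3 and 5 adjusted over the list alone (camera adjusted p = 0.117). The CD44 call was lost without DMSO 2, DMSO 3, inhibitor 1 or inhibitor 2 (limma adjusted p 0.0513 to 0.0652) and the GPC4 call without DMSO 1, DMSO 3 or inhibitor 1 (0.0546 to 0.0608). A dimmer GPC4 probe set did not pass (0.74 ± 0.32).

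Plasminogen activators moved apart: urokinase, PLAU, fell (-2.78 ± 0.41) and tissue plasminogen activator, PLAT, rose (2.48 ± 0.24). Another PLAT probe set rose by 4.31, and it represents the gene when any single DMSO array is left out (4.22 to 4.38). The metalloproteinase inhibitors TIMP3 (-2.45 ± 0.28) and TIMP2 (-1.48 ± 0.13) and the metalloproteinase ADAM12 (-2.29 ± 0.26) fell. The other rises were ADAMTS1 (1.14 ± 0.28), cystatin CST3 (0.84 ± 0.18) and the cathepsin CTSV (0.49 ± 0.10), matched to CTSL only through a synonym, so that 4 of 17 tested protease and inhibitor genes rose and 6 fell, 4 and 7 adjusted over the list alone (camera adjusted p = 0.224). The ADAMTS1 call was lost without any array other than inhibitor 3 (limma adjusted p 0.0669 to 0.128), that of CST3 without any other than DMSO 2 (0.0547 to 0.100) and that of CTSV without DMSO 1 or any inhibitor array (0.0504 to 0.0793).

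Among integrin and focal adhesion genes, ITGB5 (-1.72 ± 0.13) and ITGB3 (-3.07 ± 0.74), both partners of the alpha-v chain, fell, and ITGA9 (2.07 ± 0.26) and testin, TES (0.53 ± 0.06), rose. These were the 4 calls of 25 tested members, 3 up and 2 down adjusted over the list alone, and 7 up and 5 down with the replicate block. The list's camera adjusted p was 0.779, with a median of 0.11, a mean of -0.01 and an upward test direction. The ITGB3 call was lost without any array other than DMSO 2 (limma adjusted p 0.0624 to 0.126), without which it stood at -3.86. With the replicate block and no array left out, ITGB3 passed at limma adjusted p 0.0034. Another TES probe set did not pass (0.27 ± 0.44).

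Secreted growth factors and their binding proteins changed individually. PTN and the lymphangiogenic factor VEGFC (-2.34 ± 0.18, 5.06-fold lower) fell, as did BDNF (-1.47 ± 0.25) and IGFBP7 (-1.18 ± 0.15); neuregulin NRG1 (3.86 ± 0.61), IGFBP2 (3.38 ± 0.44, 10.4-fold higher) and endothelin EDN1 (1.75 ± 0.21) rose. Of 22 tested, 3 rose and 4 fell, 5 and 8 adjusted over the list alone, and 8 and 8 with the replicate block (camera adjusted p = 0.721, downward, with a median of 0.24 and a mean of -0.05). The NRG1 call was lost without DMSO 1 (limma adjusted p 0.0502), and its rise was 3.19 without inhibitor 2.

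In the WNT pathway list, the ligand WNT5B and the secreted DKK3 (-2.03 ± 0.31) fell and the ligand WNT2B rose (2.24 ± 0.26); a dimmer WNT2B probe set did not pass (0.86 ± 0.37). The receptor FZD4 rose 22.6-fold (4.50 ± 0.29), FZD1 (0.73 ± 0.06) and the ligand WNT9A (0.96 ± 0.16) rose, and FZD8 fell (-1.05 ± 0.13). That made 4 up and 3 down of 20 tested, 6 and 4 adjusted over the list alone, and 9 and 4 with the replicate block (camera adjusted p = 0.254). Genes induced by ERK signalling went both ways too. SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling (1.32 ± 0.14), the phosphatase DUSP1 (0.62 ± 0.10) and ETV5 (0.54 ± 0.10) rose, and the phosphatases DUSP4 (-1.74 ± 0.32) and DUSP5 (2.00-fold lower, SE 0.16 on the log2 scale), SPRED1 (-0.82 ± 0.10) and JUN (-0.36 ± 0.08) fell. Of 16 tested, these were 3 up and 4 down, 4 and 7 adjusted over the list alone, and 4 and 8 with the replicate block (camera adjusted p = 0.426). Calls were lost for DUSP1 without inhibitor 1 (limma adjusted p 0.0502), DUSP4 without DMSO 3, inhibitor 1 or inhibitor 3 (0.0577 to 0.0658), ETV5 without any array other than inhibitor 3 (0.0504 to 0.0678) and JUN without each array in turn (0.0569 to 0.0913).

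A few cell cycle genes fell by small amounts. RRM2, a ribonucleotide reductase subunit (-0.78 ± 0.11), E2F1, a transcription factor of S phase entry (-0.92 ± 0.18), the condensin subunit SMC4 (-0.38 ± 0.09) and the replication clamp PCNA (-0.35 ± 0.07) fell, 4 of 43 tested, 3 adjusted over the list alone. With the replicate block 1 rose and 10 fell. The list did not pass (camera adjusted p = 0.110, downward, and 0.716 with an estimated correlation), but did with the replicate block (0.0401), without DMSO 1 (0.0143) and without inhibitor 2 (0.0129). Among growth arrest genes, GAS2, BTG2 (-0.76 ± 0.15) and GADD45A (-0.76 ± 0.15) fell and the kinase inhibitor CDKN1B rose (0.59 ± 0.09), 4 of 14 tested; a dimmer CDKN1B probe set did not pass (0.31 ± 0.14). Adjusted over the list alone 2 rose and 3 fell, and with the replicate block 5 rose and 5 fell. The median was 0.24, the mean -0.30 and the camera adjusted p 0.780, upward. Calls were lost for E2F1 without any array other than inhibitor 2 (limma adjusted p 0.0555 to 0.0716), PCNA likewise (0.0636 to 0.0913), SMC4 without each array in turn (0.0515 to 0.104), BTG2 without DMSO 1, DMSO 3, inhibitor 1 or inhibitor 3 (0.0556 to 0.0887) and GADD45A without DMSO 1, DMSO 2, inhibitor 1 or inhibitor 3 (0.0555 to 0.0780). With the replicate block and no array left out, all of them passed in limma. The adjusted p was 0.0046 for E2F1, 0.0081 for PCNA, 0.0194 for SMC4, 0.0205 for BTG2 and 0.0048 for GADD45A.

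Several adipocyte genes rose: lipoprotein lipase, LPL (3.17 ± 0.35, 8.97-fold), ZNF423, a transcription factor of preadipocyte commitment (2.76 ± 0.23), KLF15 (2.42 ± 0.25) and the phosphatidate phosphatase LPIN1 (1.63 ± 0.28). G0S2 (-1.70 ± 0.33) and ACSL1 (-0.76 ± 0.18) fell. That is 4 up and 2 down of 13 tested, 6 and 2 adjusted over the list alone and 7 and 2 with the replicate block (camera adjusted p = 0.131, upward). The LPIN1 call was lost without DMSO 1, DMSO 3 or inhibitor 1 (limma adjusted p 0.0527 to 0.0595), that of G0S2 without the same arrays (0.0569 to 0.0807) and that of ACSL1 without any array other than DMSO 2 (0.0696 to 0.107). Of 8 tested cartilage and bone markers none passed in limma, and 2, both lower, had an unadjusted p under 0.05. The tendon transcription factor SCX stood at -2.82 ± 0.91 (limma adjusted p 0.0943, and 0.00204 with the replicate block; camera adjusted p of the list 0.254), and at -3.52 without DMSO 2, -1.90 without DMSO 3 and -3.44 without inhibitor 3.

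Markers of other cell types that embryonic skin can hold were mostly below the filter. Of the endothelial and pericyte markers 7 of 23 on the array were tested: the lymphatic genes LYVE1 (0.82 ± 0.12), PROX1 (2.67 ± 0.62) and FLT4 (2.20 ± 0.55) rose and PECAM1 fell (-0.82 ± 0.20), the same 3 and 1 adjusted over the list alone (camera adjusted p = 0.254). The PROX1 and FLT4 calls were lost without any array other than DMSO 2 (limma adjusted p 0.0741 to 0.113 and 0.0964 to 0.147), without which they stood at 3.35 and 2.88, and that of PECAM1 without each array in turn (0.0696 to 0.103). Of 6 tested leukocyte markers ARHGDIB rose (1.08 ± 0.18; lost without DMSO 3, limma adjusted p 0.0512), with 2 adjusted over the list alone (camera adjusted p = 0.224), and PTPRC, the leukocyte surface protein CD45, stood at 0.74 ± 0.22 (0.0780). Of 27 skeletal and cardiac muscle markers on the array 3 were tested: the myosin MYH15 rose (2.94 ± 0.32) and skeletal actin ACTA1 fell (-1.36 ± 0.23), also adjusted over the list alone. None of the 2 keratinocyte markers, 3 melanocyte, Schwann cell and neuron markers or the 1 tested gene of the erythroid list passed in limma. At an unadjusted p under 0.05 the counts were 0, 1 and 1, and adjusted over the list alone 0, 1 and 1; the middle list had a median of -0.09 and a mean of 0.22. The basal keratin KRT14 stood at 0.20 ± 0.42 and MITF at 0.97 ± 0.27 (limma adjusted p 0.0619, and 0.00729 with the replicate block). A dimmer MITF probe set, which does not represent the gene, passed (1.17 ± 0.28, limma adjusted p 0.0392). The tested gene of the erythroid list, ALAS1, is the form of ALA synthase found in most cells, placed on the list by a synonym match. It stood at 0.34 ± 0.09 (limma adjusted p 0.0543, and 0.0300 with the block). The globins HBA1 and HBBR lay at 2.30 and 2.53 in DMSO arrays.

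Interferon and inflammatory genes included a wide spread: the chemokine CXCL12 (-2.01 ± 0.50) and TNFAIP6 (-0.78 ± 0.14) fell and the chemokine CCL4 rose (1.15 ± 0.25), 3 of 19 tested, 1 up and 3 down adjusted over the list alone, and 3 up and 3 down with the replicate block. Interleukin IL6 stood at -3.75 ± 1.05 (limma adjusted p 0.0642, and 0.00305 with the block). It passed without DMSO 2 (-4.76, limma adjusted p 0.0297), and stood at -3.11 without inhibitor 2 and -4.57 without inhibitor 3. The list's median was 0.28, its mean -0.08 and its camera adjusted p 0.543, upward. The call of CXCL12 was lost without each array in turn (limma adjusted p 0.0540 to 0.126), that of CCL4 without any array other than DMSO 2 (0.0606 to 0.102) and that of TNFAIP6 without any single DMSO array (0.0529 to 0.0625).

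Among stress and unfolded protein genes, DNAJB9 (-1.30 ± 0.21), DNAJB11 (-0.71 ± 0.17), SDF2L1 (-0.57 ± 0.14) and HSPA5 (-0.53 ± 0.09) fell, whereas the quinone reductase NQO1 (2.21 ± 0.22) and the small heat shock protein HSPB1 (0.76 ± 0.13) rose. Of 26 tested, these were 2 up and 4 down, 2 and 5 adjusted over the list alone, and 5 and 10 with the replicate block (camera adjusted p = 0.131). Of 17 tested sterol synthesis genes FDPS fell (-0.51 ± 0.10), also adjusted over the list alone, and 4 fell with the replicate block (camera adjusted p = 0.779, downward, with a median of 0.04 and a mean of -0.05). Among 15 reference genes B2M rose (0.95 ± 0.10), also adjusted over the list alone, and with the replicate block 2 rose and 1 fell (camera adjusted p = 0.779). GAPDH stood at -0.04 ± 0.04 and ACTB at -0.02 ± 0.04. Leaving out 1 array ended the calls of DNAJB11 without any array other than inhibitor 2 (limma adjusted p 0.0837 to 0.122), SDF2L1 likewise (0.0944 to 0.146), HSPA5 without DMSO 1, DMSO 2 or inhibitor 1 (0.0502 to 0.0590), HSPB1 without DMSO 1, DMSO 3 or inhibitor 1 (0.0587 to 0.0608) and FDPS without any array other than inhibitor 2 (0.0504 to 0.0799).

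**Figure D3:**
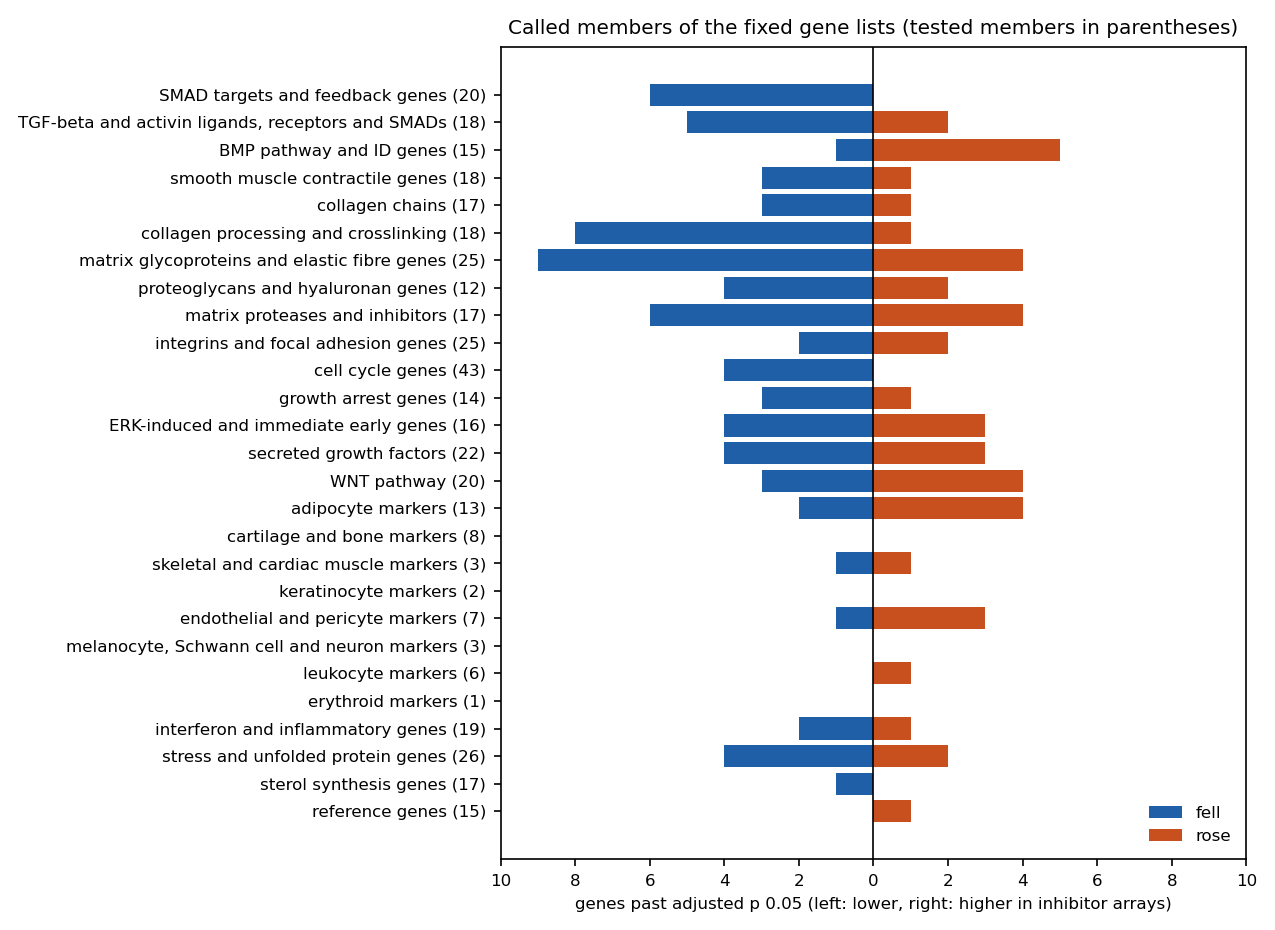
Number of members of each of the 27 gene lists that passed an adjusted p of 0.05 in limma, with falls drawn to the left and rises to the right of 0 and the tested members in parentheses. SMAD targets had 6 falls, collagen processing genes 8 falls and 1 rise, and BMP pathway genes 5 rises and 1 fall.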

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

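The leave-out of probe sets that can bind several transcripts was chosen after the data were seen; the other alternatives were planned. No called named gene and none of the 3 called lists turned direction under any of them. Of the lists that did not pass, smooth muscle, growth arrest and sterol synthesis genes turned direction under some. With median centring falls outnumbered rises (1124 probe sets up, 1229 down; 621 genes up, 701 down). Against 2283 probe sets, 1105 at 2-fold and 1273 genes called, limma gave 1285 probe sets and 706 genes with no filter, 996, 513 at 2-fold and 567 genes without moderation, and 4661 probe sets and 2570 genes with the replicate block. Leaving out 1 array gave 1107 (DMSO 1) to 1658 (inhibitor 2) probe sets, 753 to 985 at 2-fold and 624 to 917 genes. Fewer arrays or more probe sets tested lower these counts by construction. All 2283 probe sets were among the calls of the block. Of the named genes the block added 19 calls and ended none, no filter ended 38 and no moderation 66. The median of all tested probe sets moved from 0.01 to -0.01 with quantile normalization and -0.02 with median centring.

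The call of the collagen chains (camera adjusted p = 0.0402) was lost with no filter (0.263), the stricter filter (0.0886), median centring (0.0581), no trend (0.0585), no moderation (0.109), the mean of probe sets (0.0614) and fry (0.0864), and ranged from 0.00147 to 0.131 over the left-out arrays; the cause was not tested. The cell cycle list (0.110) passed with the block (0.0401) and ranged from 0.0129 to 0.319 over the left-out arrays. The block changed no other list call. The BMP list passed without probe sets that bind several transcripts (0.0353). With an estimated correlation 0 lists passed (SMAD targets 0.221, collagen chains 0.534, collagen processing 0.370), against 12 by fry. The directional p of fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. It added TGF-beta and activin genes (0.00196), matrix glycoproteins (0.0159), proteoglycans (0.000310), proteases (0.0456) and cartilage and bone markers (0.0494) downward, and BMP genes (0.000278), the WNT pathway (0.0159), adipocyte (0.000433), endothelial (0.0325) and leukocyte markers (0.0325) upward. Signal near the floor limits what could be seen: 43.1% of probe sets passed the filter.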

Other observations

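Apart from the limma results, the tests given here (the complement list and its 5 companion lists, the brightness levels, the abundant marker transcripts, the W- and Z-linked and replicate-specific probe sets, and what the splits of the arrays would show) were chosen after the values they bear on had been seen.

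Genes of complement and plasma proteins were conspicuous among the rises. Besides VTN and CFI, hemopexin HPX (4.31 ± 0.68, 19.8-fold; 5.00 without DMSO 3) and apolipoprotein APOA1 (3.91 ± 0.83; 3.04 without inhibitor 1; lost without inhibitor 3, limma adjusted p 0.0512; 6.35 to 6.48 without any single DMSO array, when another probe set that gave 6.43 represents it) rose, and so did the complement genes C7 (2.46 ± 0.21), C1S (1.98 ± 0.12) and C1R (1.89 ± 0.17) and ceruloplasmin, CP (1.02 ± 0.19; 0.66 ± 0.30 by another probe set, which did not pass; lost without DMSO 1, DMSO 2 or inhibitor 1, limma adjusted p 0.0517 to 0.0637), whereas transferrin, TF, fell (-0.98 ± 0.14). The DMSO means of HPX and C7, like those of VTN and of PDE1A named next, were under 4, so that their folds depend on the GCRMA floor. Of 14 tested genes of such a list 8 rose and 1 fell (camera adjusted p = 7.70e-05 over 6 lists written for this purpose). Without the 45 largest changes each way, which had prompted the list, 4 of 10 rose and 1 fell with a median of 0.87 (camera adjusted p = 0.0253, 0.0276 with the replicate block, and adjusted p = 0.243 with an estimated correlation). A shared rise of these genes is therefore a hypothesis that these data may favour but did not test independently.

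Some genes of cyclic nucleotide signalling were among the largest changes. NPR3, the phosphodiesterase PDE1A (3.41 ± 0.77) and PKIG, an inhibitor of protein kinase A (3.06 ± 0.37), rose, and PDE4D, the adenylyl cyclase ADCY2 (-3.20 ± 0.32) and PDE4B (-1.66 ± 0.31) fell. Of 36 such genes 4 rose and 6 fell, and without the 45 largest changes each way 1 of 31 rose and 4 fell, and the list did not pass (camera adjusted p = 0.361). The call of PDE1A was lost without any array other than DMSO 2 (limma adjusted p 0.0545 to 0.117; 4.08 without DMSO 2 and 2.72 without inhibitor 2) and that of PDE4B without DMSO 1, DMSO 3, inhibitor 2 or inhibitor 3 (0.0550 to 0.0694), and a dimmer PDE4B probe set did not pass (-1.28 ± 0.33). Of the companion lists, axon guidance genes (0.446), solute carriers (0.210) and RGS and G protein subunit genes (0.417) did not pass either.

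Among the brightest probe sets few differences were large: 0 of the 155 brightest tested probe sets passed limma with a 2-fold difference, against 133 of 2676 (4.97%) with a mean between 10 and 12 (Fisher's exact p = 0.000708). In 4 genes with such a bright probe set and a called dimmer one (TPM1, FN1, FZD1 and SLC25A6) the bright probe set showed a median share of 0.163 of the dimmer one's change, against 0.818 in 76 genes of middle brightness (exact rank-sum p = 0.0193). That p rests on 4 genes and counts the opposite sign of FN1 as a low share, so it does not by itself favour compression. Compression of the signal near the top of the range would give the low shares of TPM1 (0.159 to 0.292) and SLC25A6 (0.131), but not that of FZD1 (0.827) or the opposite sign of FN1 (-0.178 and -0.193), and isoforms remain an alternative for TPM1 and FN1. Whether abundant transcripts also changed less cannot be told apart from this: dimmer probe sets of the brightest genes were called in 7 of 57 cases (12.3%), against 86 of 991 (8.68%; Fisher's exact p = 0.337). The 57 came from 31 genes, the 991 from 709 genes and the 7 calls from 4 genes. Both Fisher tests count probe sets of the same gene as separate cases, so their p-values are only rough. Small values of CCN2, COL1A1, COL3A1, FN1, GAPDH and ACTB, each represented by 1 of these 155 probe sets, may understate a change if compression holds for them, which was not tested. Dimmer probe sets of COL3A1 (-0.05 ± 0.13 to 0.27 ± 0.45) and ACTB (-0.10 ± 0.20 and 0.04 ± 0.10) did not pass in limma. They gave no sign of a hidden change in COL3A1 or ACTB.

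KRT7, CFI, VTN, ARHGAP15, EXFABP and TNFSF4 rose by 4.86 or more on the log2 scale (lowest bound of the 6 at 2 SE, 3.06), and epithelial or blood cells among the cultures could carry some of them. In a fit over all probe sets, the largest difference among 6 abundant keratinocyte transcripts was 0.20 ± 0.43 (KRT14), with 5 of them under 4 in both groups. Among 9 abundant leukocyte transcripts it was 0.82 ± 0.74 (C1QB), with 8 under 4. Floor values cannot tell absent cells from probe sets that fail to detect their transcript. These values argue against either cell type as the source of rises this large only if those probe sets work, which was not examined. Neither cell type is excluded by them. Leukocyte markers above the floor were higher by less than these rises, ARHGDIB by 1.08 ± 0.18 and PTPRC, which did not pass, by 0.74 ± 0.22, and with fry's upward adjusted p of 0.0325 for the list a small rise in leukocytes stays open. Both marker lists were first examined as a median over all markers (-0.01 and -0.00), which says little because most lie at the floor; KRT24, matched to KRT19 through a synonym, went from 2.22 to 4.47. A change within the myofibroblasts and all other cell types, endothelial and muscle cells among them, which were not tested as a source, stay open, as does a difference in cell makeup that 3 cultures per group share.

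Replicate 2 of both groups differed from the others in genes of the W chromosome, which only hens carry: HINTW stood at 14.6 and 14.3 in DMSO 2 and inhibitor 2 and at 1.92 to 1.98 in the other 4 arrays, and 17 W-linked probe sets of 11 genes were over 3 log2 units higher in both. Z-linked probe sets, of which hens carry a single copy, lay lower there too, at -0.38 and -0.31 relative to the numbered chromosomes against 0.12 to 0.25 elsewhere (difference -0.53; 649 probe sets). This is consistent with same-numbered cultures sharing embryos, with replicate 2 from female embryos. A single mislabelled array is argued against, as 43 probe sets stood over 3 log2 units apart in both arrays of a number and 0 in any pair of unlike numbers, with 6 in a single array. Whether the response to the inhibitor differs with sex was not tested.

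The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split, and no other, gave 2283 probe sets, 1105 at 2-fold and 1273 genes, so that 1 of 10 splits reached each of these counts and the highest of the others was 0. Every other split mixes inhibitor and DMSO arrays within a group. The inhibitor difference then adds to the spread within groups and lowers the counts by construction, so these 0 counts do not measure chance. The real split called 3 gene lists, 4 of the 10 splits called as many, and the highest other was 5. Of the 4 splits that part all same-numbered arrays, the other 3 called 0 probe sets and at most 3 lists. In the real comparison limma gave 4862 probe sets at an unadjusted p under 0.05.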
